A study of Mus musculus with 12 samples.

How the data were processed

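The scanner files of 12 one-colour arrays were read as deposited, and per the file headers they came from Agilent Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09. The deposited processed signal is a background-corrected intensity on the linear scale per the file headers, and its log2 was taken here. Each array's own 75th percentile on the log2 scale was then subtracted, so a level of 0 means the brightness of that percentile. Levels are relative to other genes on the same array and do not measure RNA per cell.

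Each array held 44397 features, of which 43020 were not controls. Spots marked as outliers by the extraction software were set to missing (2469 spot values over all arrays), no spot was saturated, and spots of one probe were averaged to 39429 probes under 31541 gene names. A probe was kept where it was well above background on both arrays of at least 1 group, by the software's own mark. This left 18556 genes, and 3907 of them had several kept probes. Each of these was represented by its probe with the highest mean level. Where another kept probe differed by over 1 on the log2 scale from a printed change of a gene named by its own change, by a bound or always, that probe's change is printed too. Members of lists are mostly given by 1 probe alone. Whether a probe measures the transcript it is named for was not tested. The Csf3r probe lay at similar levels in all 6 groups, so its changes near 0 do not show that the transcript was unchanged.

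Gene names are those of the array annotation, and some are older names: Sfpi1 is now Spi1, Igj is Jchain, Gpr97 is Adgrg3, Gcom1 is Myzap and Faim3 is Fcmr. The RefSeq table of assembly GRCm38.p6 was used for names only. By accession, 12985 of the kept genes matched it, and 1441 of those carry another symbol there. A further 6268 kept genes are named by a clone or accession number alone and are never named in the text. Probe locations are those of the array annotation, on mm9.

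Changes were tested with limma 3.58.1 (lmFit and eBayes, default prior) in R 4.3.3, with data.table (version 1.17.8) and jsonlite (2.0.0). A single model held all 12 arrays in 6 groups of 2, so every comparison shares 1 estimate of the spread, with 6 residual and 2.15 prior degrees of freedom. The spread was not equal. The median standard deviation between replicates was 0.221 in hCD4- pre-pro-B arrays and 0.098 to 0.152 in the other groups. The shared estimate can therefore understate the error of comparisons with the hCD4- pre-pro-B arrays. Tests were two-sided, p-values were adjusted over genes by the Benjamini-Hochberg method within each comparison, and a gene is said to have risen or fallen where the adjusted p was under 0.05. Errors given with changes are standard errors on the log2 scale from that model, and errors given with levels are standard deviations over the 2 arrays of a group. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

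Before the data were examined, the groups, the 8 comparisons, the tests, the 24 gene lists, the rule for naming genes and most alternatives were chosen. The rule names the 8 largest rises and 8 largest falls of a comparison among genes that pass the test, are well above background on at least 1 array of both groups and show no overlap of the 2 groups' arrays. It adds the 4 largest lower bounds in each direction among genes that no array of one group measured above background. For the difference of the hCD4 contrasts and for hCD4+ pro-B against hCD4+ pre-pro-B arrays it names 4 in each direction, and for GMP against pre-B arrays none. Cebpa, Cebpe, Csf1r, Csf3r, Mpo, Elane, Irf8, Sfpi1, Ebf1, Pax5, Rag1, Il7r and Flt3 are among those always named, and up to 4 members with the largest changes may be named from each list. A few genes that these rules would name are not reported here. "At least N-fold" means that the dimmer group was not well above background on any array. The bound then sets the dimmer group to the level of the dimmest probe still well above background on its arrays.

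The lists are myeloid transcription factors and receptors, neutrophil primary granule genes, neutrophil secondary granule and late genes, monocyte genes, classical dendritic cell genes, plasmacytoid dendritic cell genes, natural killer cell genes, T cell genes, erythroid genes, megakaryocyte genes, basophil, mast cell and eosinophil genes, stem and multipotent progenitor genes, early lymphoid progenitor genes, B lineage transcription factors, pro-B cell genes, pre-B and later B cell genes, plasma cell genes, S phase genes, G2/M phase genes, interleukin 7 and STAT5 response genes, interferon response genes, immediate early and handling stress genes, antigen presentation class II genes and glycolysis genes. Each was ranked against all other kept genes with camera at an inter-gene correlation of 0.01, where at least 5 members were kept, and adjusted over all 192 tests. Some lists share genes, so their calls are not independent. At this setting 83 of the 192 tests passed, and with a correlation estimated from the residuals none did, so that adjusted p is printed beside each call. For the set tests 21 missing values were filled with the mean of the gene's other array in the group.

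The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, the array median in place of the 75th percentile, the authors' table, no filter, a stricter filter (at least 6 arrays), the mean of a gene's probes, only the arrays compared, a block for replicate number, an intensity trend in the prior, array weights, a log2 change of at least 1, and 12 fits that each left out 1 array. For lists, camera with estimated correlation and fry were run. For the GMP signature a minimum log2 difference of 3 replaced 2. Cyclic loess, a filter for genes measured on every array compared, comparisons within a slide and a list of immunoglobulin genes were added after the data were seen. A slide block could not be fitted, because each group lay on a single slide, and a scan date block would have been the same as the slide.

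The authors' deposited table gives log2 values of intensity, and its labels do not state the normalization. Its median was 6.5 on every array, and its correlation with the log2 scanner values lay between 0.940 and 0.954.

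The same steps were also run on simulated values with each gene's fitted group means and spread, in which the 2 groups of a contrast were given equal means and changes of known size were planted. In the pre-pro-B contrast 34 of 67 planted genes were recovered at a log2 size of 1, 60 of 67 at 2 and 64 of 66 at 4, with 5 false calls among 18535 genes. In the pro-B contrast 30 of 67, 60 of 67 and 65 of 66 were recovered, with 9 false calls. The simulated noise was independent between genes and arrays, with no slide effect and the same spread in every group. The real arrays need not have so few false calls.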

Results

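Marrow cells of female C57BL/6 mice, 16 weeks old, carrying a human CD4 (hCD4) reporter under Cebpa enhancer and promoter sequence were sorted by surface markers, and their RNA was amplified, labelled with Cy3 and measured on mouse expression arrays. Per the labels the groups are granulocyte-monocyte progenitors (GMP) positive for hCD4, pre-pro-B and pro-B cells each negative or positive for hCD4, and pre-B cells whose hCD4 status is not stated. Each of the 6 groups has 2 arrays. The labels do not tie replicate numbers to single animals, so p-values measure the spread between these samples, and the number of arrays limits the precision.

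The arrays lie on 3 slides of 4: GMP and hCD4- pre-pro-B on the first, hCD4+ pre-pro-B and hCD4- pro-B on the second, hCD4+ pro-B and pre-B on the third. Each slide was scanned in a single run, so slide and group cannot be told apart in any of the 8 comparisons chosen beforehand. Replicates correlated at 0.982 to 0.992, and means of different groups at 0.852 to 0.977. Between 50.6% and 56.7% of probes were well above background. The hCD4- pre-pro-B arrays were the dimmest, with a 75th percentile of 302 against 799.9 for GMP, 728 for hCD4+ pre-pro-B, 671 for hCD4- pro-B, 642 for hCD4+ pro-B and 537 for pre-B arrays. Their spike-in controls lay highest above that percentile, by 5.06 on the log2 scale against 1.95 to 3.93 in the other groups. The net signal of negative controls was higher on slide 3 than on the other slides.

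Cebpa, which encodes a transcription factor of the myeloid lineage and whose regulatory sequence drives the reporter, was brightest in GMP (log2 level 1.78, standard deviation 0.27, n = 2). It lay at -0.97 (0.62) in hCD4- and -0.49 (0.20) in hCD4+ pre-pro-B arrays. In hCD4+ pro-B arrays it lay at -1.69 (0.35), while neither array measured it above background in hCD4- pro-B (-6.10, 1.03) and pre-B (-5.92, 0.48). Its probe lies on chromosome 7 at 35906517 to 35906576 (mm9). Between hCD4+ and hCD4- arrays it rose in pro-B cells, by 4.41 (standard error 0.49, adjusted p = 9.64e-04), at least 8.75-fold. In pre-pro-B cells the change was 0.48 (0.49, adjusted p = 0.529).

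**Figure D1:**
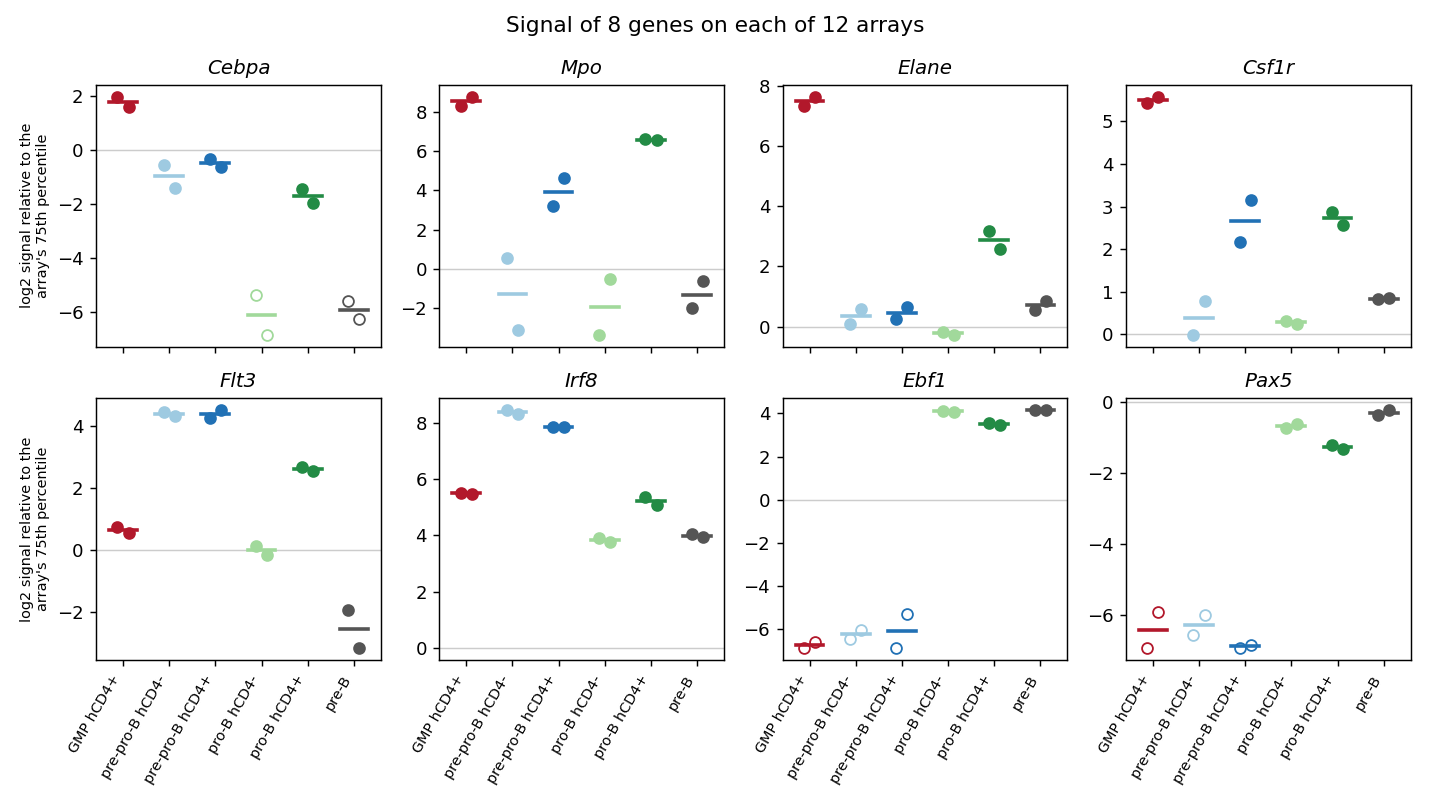
Log2 signal relative to the array's 75th percentile (vertical axis) of Cebpa, Mpo, Elane, Csf1r, Flt3, Irf8, Ebf1 and Pax5 on 12 arrays, by group (horizontal axis). Bars are means of 2 arrays, and open circles mark groups in which no array was well above background. Cebpa means run from -6.10 in hCD4- pro-B to 1.78 in GMP arrays, and Irf8 means from 3.83 to 8.38.

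In pre-pro-B cells, genes of the cell cycle and some genes of myeloid granules were higher on hCD4+ than on hCD4- arrays (2 against 2). Mpo, the granule peroxidase, rose by 5.24 on the log2 scale (standard error 1.26, adjusted p = 0.0265), from -1.32 (standard deviation 2.59) to 3.92 (1.00), and its second probe by 4.53. Over its alternatives the rise of Mpo ran from 3.40 to 7.07. The protease gene Ctsg rose by 4.95 (0.83, adjusted p = 0.00647), Rab44 by 4.74 (0.37, adjusted p = 1.19e-04) and the kinase gene Cdk1 by 3.23 (0.12, adjusted p = 1.23e-05; other probes 1.17 and 1.58). Cd34 rose by 3.43 (0.97; other probe 0.96), Nuf2 by 3.37 (0.45), Cenpn by 3.36 (0.51) and the platelet gene Pf4 by 3.35 (0.87; 1.86 to 4.85 over its alternatives). Ctsg, Rab44, Nuf2, Cenpn and Pf4 were above background on 1 of 2 hCD4- arrays. F13a1 was at least 12.03-fold higher (adjusted p = 1.36e-06; other probe -0.63), Ccl9 at least 8.75-fold, Lyz1 at least 7.65-fold and Hp at least 7.11-fold.

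The largest falls in hCD4+ pre-pro-B arrays were in antibody transcripts. Igh-VJ558 fell by 9.91 (standard error 1.58, adjusted p = 0.00514), with -10.98, -5.72 and -0.70 at 3 other probes. Igj, the joining chain, fell by 5.48 (0.82, adjusted p = 0.00361). Smaller falls were those of Elk4 (-2.88, 0.71; other probes -0.75 and -0.66), Cacna1e (-2.38, 0.25), Slc13a4 (-2.24, 0.33), Cacna1d (-2.19, 0.37, other probe -1.13), Cblc (-2.08, 0.50) and the granule gene Camp (-2.08, 0.41). Igfbp7 was at least 7.67-fold lower, Slc4a5 at least 7.41-fold, Zan at least 5.56-fold and Pgk2 at least 5.52-fold. Among reference genes Csf1r, the receptor for macrophage colony-stimulating factor, rose by 2.27 (0.33, adjusted p = 0.00344), while its other probes gave -0.73 and -0.05. Irf8 fell by 0.53 (0.12, adjusted p = 0.0248). Values without a call were Cebpe 1.66 (0.53, adjusted p = 0.0668), Elane 0.11 (0.26), Csf3r -0.05 (0.19), Sfpi1 0.40 (0.29), Rag1 -0.00 (0.35, other probe -1.35), Il7r -0.17 (0.14) and Flt3 0.01 (0.33). Ebf1 and Pax5, genes of the committed B lineage, were not above background in either group.

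Of the G2/M phase genes 21 of 22 rose in hCD4+ pre-pro-B arrays, 21 adjusted over the list alone, with a median of 2.39 (adjusted p = 3.94e-23, or 0.122 with an estimated correlation). Top2a rose by 3.09 (0.41) and Birc5 by 2.59 (0.17). Of the S phase genes 21 of 23 rose, 21 adjusted over the list alone, with a median of 1.56 (adjusted p = 7.86e-21, or 0.122 with an estimated correlation), among them E2f8 (2.69, 0.11), Rrm2 (2.59, 0.12) and Cdc6 (2.27, 0.17). Monocyte genes had 7 of 13 higher, 7 adjusted over the list alone (median 1.04, adjusted p = 1.05e-06, or 0.122 with an estimated correlation), with Fn1 at least 5.90-fold higher and Cx3cr1 up by 2.83 (0.30; other probe 3.86). Neutrophil primary granule genes had 7 of 14 higher and 0 lower, or 7 and 1 adjusted over the list alone (median 1.10, adjusted p = 0.00591, or 0.251 with an estimated correlation), with Prtn3 at least 5.48-fold higher. In the interleukin 7 and STAT5 response genes 4 of 11 rose, 4 adjusted over the list alone (median 0.54, adjusted p = 0.0379, or 0.448 with an estimated correlation), led by Myc (1.49, 0.37), Bcl2 (1.28, 0.27) and Ccnd3 (1.06, 0.15). The median of this list ran from 0.14 to 0.84 over its alternatives. It was 0.00 with levels under the detection floor set to that floor.

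Lists that lay lower in hCD4+ pre-pro-B arrays held few genes that passed alone. Plasmacytoid dendritic cell genes had a median of -0.49 with 1 of 18 lower (Lair1, -0.81, 0.20, other probe -0.17), 0 adjusted over the list alone (adjusted p = 0.00591, or 0.431 with an estimated correlation). Pre-B and later B cell genes had 2 of 19 lower, 2 adjusted over the list alone (median -0.55, adjusted p = 0.0121, or 0.331 with an estimated correlation). Interferon response genes had 5 of 20 lower, 6 adjusted over the list alone (median -0.37, adjusted p = 0.0131, or 0.488 with an estimated correlation), among them Ifit2 (-1.15, 0.20). The other lists were not called. Their medians were 0.16 for myeloid transcription factors and receptors (adjusted p = 0.543), -0.85 for neutrophil secondary granule and late genes (0.279), 0.05 for classical dendritic cell genes (0.686), -0.50 for class II genes (0.0981) and 0.25 for stem and multipotent progenitor genes (0.262). They were -0.25 for natural killer cell, -0.41 for T cell, 0.31 for erythroid, 0.15 for basophil, mast cell and eosinophil and -0.30 for plasma cell genes. They were -0.01 for early lymphoid progenitor genes, -0.23 for B lineage transcription factors, 0.02 for pro-B cell, 0.33 for immediate early and handling stress and 0.14 for glycolysis genes. Megakaryocyte genes had a median of -0.26 and a mean of 0.29, with 2 higher and 1 lower of 8.

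In all, 3162 of 18556 genes differed between the pre-pro-B groups (1629 higher, 1533 lower). Leaving out 1 array moved this to 5319 (hCD4- replicate 1), 1632 (hCD4- replicate 2), 1710 (hCD4+ replicate 1) or 1120 (hCD4+ replicate 2), and a fit to these 4 arrays alone gave 485. Scaling to the array median put 83.4% of the changed genes higher and cyclic loess 68.4%, against 51.5% here. Without hCD4+ replicate 2 the calls of Mpo (adjusted p = 0.147), Ctsg (0.0520), Cd34 (0.209), Pf4 (0.109), Elk4 (0.158), Cacna1d (0.0522), Cblc (0.131), Camp (0.0863), Pgk2 (0.0883), Irf8 (0.120) and the interleukin 7 list (0.152) ended. Without hCD4+ replicate 1 those of Mpo (0.0623), Cd34 (0.0928), Pf4 (0.139), Elk4 (0.0583), Cblc (0.0854), Pgk2 (0.0789) and Irf8 (0.0938) ended. Without hCD4- replicate 2 those of Mpo (0.120), Cd34 (0.129), Pf4 (0.105), Elk4 (0.0838), Cblc (0.0838), Camp (0.0652) and Pgk2 (0.0817) ended. Without hCD4- replicate 1 those of Cd34 (0.0973), Elk4 (0.0694), Cblc (0.0640), Irf8 (0.0546), the interferon list (0.0674) and the interleukin 7 list (0.152) ended. Arrays of other groups ended Cd34 (0.0631 without either GMP array, 0.0681 without either pre-B array, 0.0713 without either hCD4+ pro-B array) and Pf4 (0.0526 without either pre-B array, 0.0538 without either hCD4- pro-B array). With only the arrays compared, the calls of Mpo (0.143), Ctsg (0.104), Nuf2 (0.0846), Cenpn (0.104), Pf4 (0.184), Elk4 (0.0567), Ccl9 (0.0502), Hp (0.0653), Igfbp7 (0.0933), Csf1r (0.0983) and Irf8 (0.159) ended. Without the filter those of Cd34 (0.0735), Pf4 (0.0616), Elk4 (0.0537), Cblc (0.0514), Slc4a5 (0.171) and Irf8 (0.0612) ended, and with array weights those of Mpo (0.0817), Cd34 (0.219), Pf4 (0.0544), Elk4 (0.126), Cblc (0.125), Camp (0.0737), Pgk2 (0.0656) and Irf8 (0.0858). With the replicate number as a block Cd34 ended (0.0535). Over its alternatives the adjusted p of Mpo ran from 0.00476 to 0.147, of Ctsg from 7.44e-04 to 0.104, of Cd34 from 0.00102 to 0.219, of Pf4 from 0.00226 to 0.184, of Irf8 from 0.00913 to 0.645 and of Csf1r from 7.59e-04 to 0.153. Those of Elk4 ran from 0.00573 to 0.158, of Cacna1d from 0.00111 to 0.0522, of Cblc from 0.0157 to 0.131, of Camp from 0.00617 to 0.0863 and of Pgk2 from 0.00330 to 0.0883. The interleukin 7 list ran from 0.00630 to 0.164 and the interferon list from 0.00317 to 0.0674. Irf8 changed less under other normalizations, without a call: by -0.15 with normexp and quantile normalization (adjusted p = 0.418), -0.10 with quantile normalization (0.645), -0.22 with array-median scaling (0.354) and -0.10 in the authors' table (0.612). The interleukin 7 list ended with normexp and quantile normalization (0.164), quantile normalization (0.0558), array-median scaling (0.0780), the authors' table (0.0718) and cyclic loess (0.0987). With the mean of its probes Csf1r stood at 0.50 (adjusted p = 0.153) and in the authors' table at 0.50 (0.102).

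In pro-B cells, genes of myeloid and dendritic cells were higher on hCD4+ than on hCD4- arrays (2 against 2). Mpo rose by 8.56 (standard error 1.26, adjusted p = 0.00324), from -1.96 (standard deviation 2.02) to 6.61 (0.07). Ctsg rose by 6.84 (0.83, adjusted p = 0.00134), Cd34 by 6.04 (0.97, adjusted p = 0.00461; other probe 0.46) and the chemokine receptor gene Cx3cr1 by 5.05 (0.30, adjusted p = 7.36e-05). Itgax, a dendritic cell integrin, rose by 4.61 (0.68), Lgals3 by 4.44 (0.22) and Cd209a by 4.24 (0.82; other probe 1.34). Cd34, Cx3cr1 and Cd209a were above background on 1 of 2 hCD4- arrays. Prtn3 was at least 63.8-fold higher (adjusted p = 1.61e-04), Ms4a3 at least 56.9-fold, Ms4a6c at least 25.1-fold and Aif1 at least 17.2-fold. Among reference genes Cebpe rose by 3.17 (0.53, adjusted p = 0.00543), Elane by 3.097 (0.26, adjusted p = 2.87e-04), Irf8 by 1.38 (0.12, adjusted p = 4.00e-04), Csf1r by 2.44 (0.33; other probes 2.26 and 0.99) and Flt3, a progenitor cytokine receptor, by 2.63 (0.33; other probes 2.65 and 0.58).

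Falls in hCD4+ pro-B arrays again began with antibody transcripts. Igh-VJ558 changed by -8.45 (1.58, adjusted p = 0.00887, other probes -8.47, -4.67 and -0.72) and Igj by -7.35 (0.82, adjusted p = 9.43e-04). S100a9 (-6.53, 1.44, adjusted p = 0.0167) and Ltf (-4.80, 0.66), genes of mature neutrophils, Grb7 (-4.03, 0.22, adjusted p = 6.20e-05), Klhl32 (-2.91, 0.25), the follicle-homing receptor gene Cxcr5 (-2.82, 0.29) and Gchfr (-2.68, 0.16) followed. Igh-VJ558, Igj, S100a9, Ltf and Cxcr5 were above background on 1 of 2 hCD4+ arrays. Heyl was at least 11.6-fold lower, Speer2 at least 5.86-fold, Ngp at least 5.60-fold and Klra7 at least 5.10-fold. Values of B lineage reference genes without a call were Ebf1 -0.56 (0.43, adjusted p = 0.388), Pax5 -0.60 (0.31), Rag1 -0.88 (0.35) and Il7r -0.34 (0.14). Sfpi1 stood at 0.93 (0.29, adjusted p = 0.0555) and Csf3r at 0.05 (0.19).

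Of the myeloid transcription factors and receptors 11 of 15 rose and 1 fell in hCD4+ pro-B arrays, 12 and 2 adjusted over the list alone (median 1.81, adjusted p = 2.06e-06, or 0.153 with an estimated correlation), with the adaptor genes Fcer1g (3.44, 0.20) and Tyrobp (3.42, 0.35). Of the monocyte genes 8 of 13 rose, 10 adjusted over the list alone (median 1.50, adjusted p = 3.28e-07, or 0.122 with an estimated correlation), with Ccr2 at least 13.5-fold higher and S100a4 up by 3.09 (0.25). Neutrophil primary granule genes had 9 of 14 higher and 2 lower, the same adjusted over the list alone (median 2.20, adjusted p = 2.81e-04, or 0.167 with an estimated correlation). Classical dendritic cell genes had 7 of 8 higher, or 7 higher and 1 lower adjusted over the list alone (median 3.095, adjusted p = 5.73e-04, or 0.249 with an estimated correlation), with Clec9a at least 8.08-fold higher and Clec10a up by 3.56 (0.70). Plasmacytoid dendritic cell genes had 12 of 18 higher and 2 lower, 13 and 2 adjusted over the list alone (median 1.22, adjusted p = 6.07e-05, or 0.251 with an estimated correlation), with Runx2 at least 6.57-fold higher and Klk1 up by 2.88 (0.76). Basophil, mast cell and eosinophil genes had 4 of 11 higher, 4 adjusted over the list alone (median 1.41, adjusted p = 0.0110, or 0.153 with an estimated correlation), with Hdc (2.24, 0.46) and Cpa3 (2.16, 0.48). Class II genes had 4 of 10 higher and 1 lower, 7 and 2 adjusted over the list alone (median 1.28, adjusted p = 0.0395, or 0.448 with an estimated correlation), with H2-DMb1 (1.69, 0.19). Glycolysis genes had 1 of 16 higher (Eno1, 0.67, 0.14), 1 adjusted over the list alone (median 0.33, adjusted p = 0.0224, or 0.448 with an estimated correlation).

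Lower in hCD4+ pro-B arrays were neutrophil secondary granule and late genes, with 7 of 14 lower and 2 higher, 9 and 2 adjusted over the list alone (median -1.56, adjusted p = 0.00233, or 0.251 with an estimated correlation). S100a8 stood at -5.18 (1.58, adjusted p = 0.0522). Pro-B cell genes had 5 of 23 lower, 5 adjusted over the list alone (median -0.51, adjusted p = 4.08e-05, or 0.260 with an estimated correlation), with Enpep at least 3.79-fold lower and Bst1 down (-0.91, 0.17). B lineage transcription factors had 6 of 16 lower and 1 higher, 7 and 1 adjusted over the list alone (median -0.60, adjusted p = 0.00604, or 0.249 with an estimated correlation), with Irf4 (-1.23, 0.16) and Bach2 (-1.11, 0.25). Pre-B and later B cell genes had 8 of 19 lower and 2 higher, 8 and 4 adjusted over the list alone (median -0.26, adjusted p = 0.0368, or 0.431 with an estimated correlation), with Cd40 (-1.86, 0.46), Ms4a1 (-1.69, 0.16) and Cd72 (-1.48, 0.13). Interferon response genes had 5 of 20 lower and 2 higher, 9 and 3 adjusted over the list alone (median -0.47, adjusted p = 0.00809, or 0.480 with an estimated correlation), with Ifit3 (-1.78, 0.25) and, higher, Bst2 (1.13, 0.27). The cell cycle lists were not called: 0 of 23 S phase genes passed (median 0.13, adjusted p = 0.492) and 2 of 22 G2/M phase genes fell (median -0.19, adjusted p = 0.142). Among the T cell genes 3 rose and 2 fell (median 0.20, adjusted p = 0.835), with Cd8a at least 1.96-fold higher and Cd3d at least 2.26-fold lower. Early lymphoid progenitor genes had a median of -0.07 and a mean of 0.24.

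**Figure D2:**
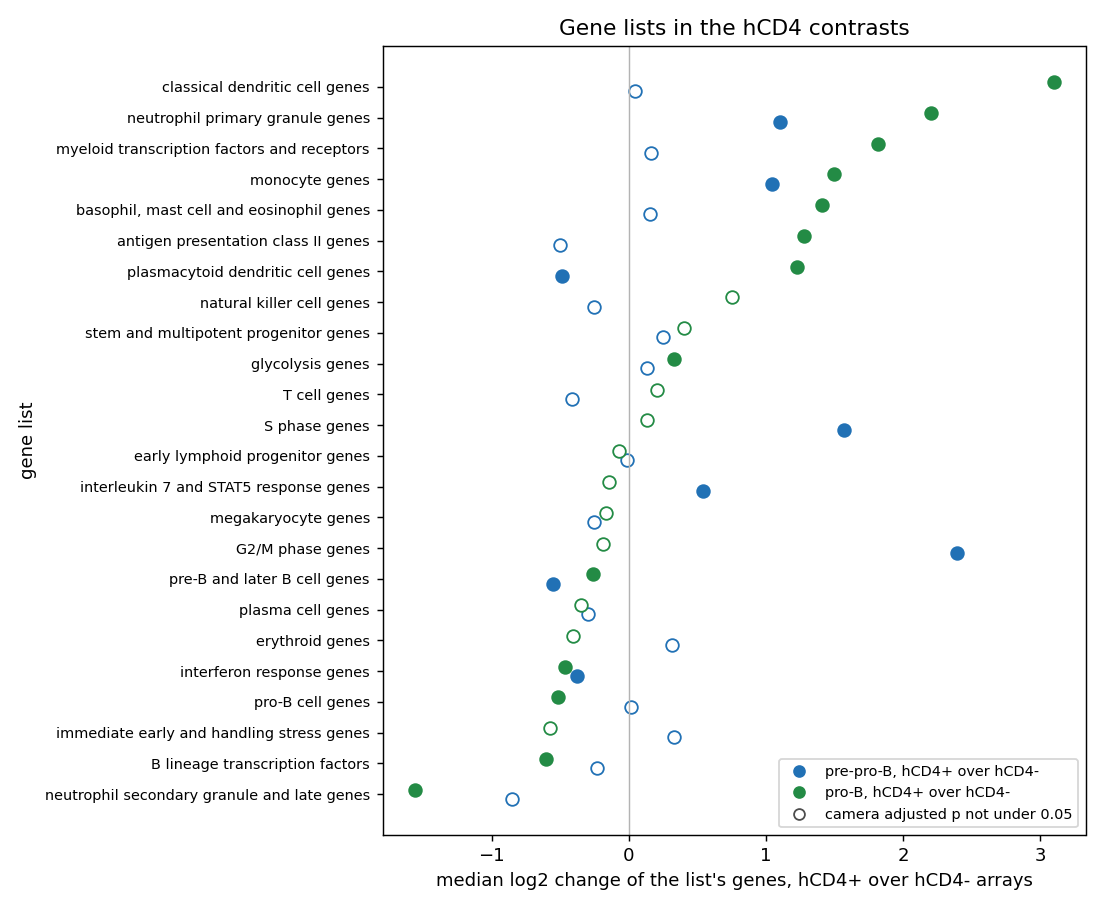
Median log2 change between hCD4+ and hCD4- arrays (horizontal axis) of 24 gene lists (vertical axis) in pre-pro-B (blue) and pro-B cells (green), 2 arrays per group. Open circles mark lists whose camera adjusted p was not under 0.05. Medians run from -0.85 to 2.39 in pre-pro-B and from -1.56 to 3.095 in pro-B cells.

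In pro-B cells 3802 genes differed between hCD4+ and hCD4- arrays (2158 higher, 1644 lower). The count fell to 1974 without hCD4- replicate 1, 1460 without hCD4- replicate 2, 1861 without hCD4+ replicate 1 and 1943 without hCD4+ replicate 2. Scaling to the array median put 31.1% of changed genes higher against 56.8% here. Without hCD4- replicate 1 the calls of S100a9 (adjusted p = 0.0825) and the pre-B list (0.0575) ended. Without hCD4- replicate 2 those of S100a9 (0.0678), Cd209a (0.0565), Igh-VJ558 (0.0516), Klra7 (0.0515) and the class II list (0.0644) ended. Without hCD4+ replicate 1 those of Cd209a (0.0565), Klra7 (0.0570) and the class II list (0.137) ended, and without hCD4+ replicate 2 those of S100a9 (0.0887), Cd209a (0.0513) and the pre-B list (0.189). Over the alternatives the adjusted p of S100a9 ran from 0.00378 to 0.0887, of Cd209a from 5.86e-04 to 0.0565, of Igh-VJ558 from 3.56e-04 to 0.0533 and of Klra7 from 2.32e-04 to 0.0570. The class II list ran from 0.0142 to 0.137, the pre-B list from 0.00337 to 0.189 and the glycolysis list from 0.00337 to 0.108, the last under array-median scaling. The pre-B list also ended under that scaling (0.103) and with the replicate number as a block (0.0567), and Igh-VJ558 with only the arrays compared (0.0533).

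Genes that part GMP from pre-B arrays by at least 2 on the log2 scale were counted in both hCD4 contrasts. Of 1494 GMP genes 230 (15.4%) rose and 44 (2.95%) fell in hCD4+ pre-pro-B arrays, with a median of 0.10 (camera p = 5.74e-04, or 0.147 with an estimated correlation). In hCD4+ pro-B arrays 578 (38.7%) rose and 15 fell, with a median of 0.58 (p = 2.01e-22, or 0.00325 with an estimated correlation). Of 1696 pre-B genes 304 (17.9%) fell and 63 rose in hCD4+ pre-pro-B arrays (median -0.44, p = 2.48e-08, or 0.0296 with an estimated correlation). There the 4639 dimmest genes had a median of -0.33, so this fall may not be limited to pre-B genes. In hCD4+ pro-B arrays 530 (31.3%) fell and 151 rose (median -0.47, p = 7.54e-12, or 0.0130 with an estimated correlation). The contrasts had 319 higher genes in common, Mpo, Ctsg and Cd34 among them, where 189 would be shared by chance (Fisher's exact p = 1.54e-22). They shared 176 lower genes, Igh-VJ558 and Igj among them, where 136 would be (2.94e-04), while 344 genes were called in opposite directions, where 323 would be by chance. Across all genes the log2 changes of the contrasts correlated at 0.0922. The values expected by chance and Fisher's test treat genes and contrasts as independent. Both contrasts use the same estimate of each gene's spread, so these p-values can be too small.

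**Figure D3:**
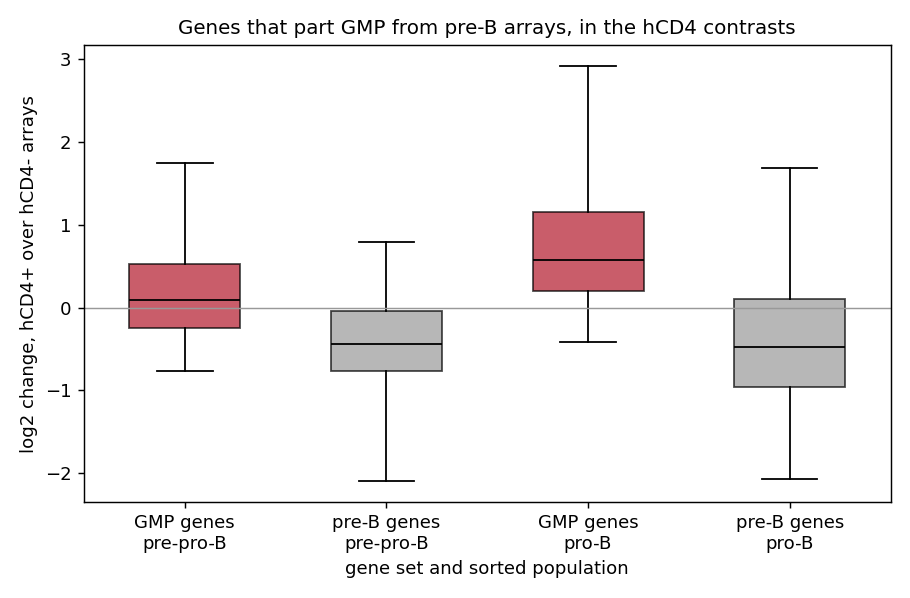
Log2 change between hCD4+ and hCD4- arrays (vertical axis) of 1494 GMP genes and 1696 pre-B genes in pre-pro-B and pro-B cells (horizontal axis). Lines inside the boxes are medians (0.10, -0.44, 0.58 and -0.47 from left to right), boxes span the quartiles, and whiskers run from the 5th to the 95th percentile.

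The hCD4 contrast of pro-B cells exceeded that of pre-pro-B cells for dendritic and class II genes and lay under it for cell cycle genes. Median levels of classical dendritic cell genes were 3.29 and 3.17 in hCD4- and hCD4+ pre-pro-B arrays, and -2.59 and 0.67 in the pro-B groups. Those of plasmacytoid dendritic cell genes were 5.20 and 4.82 against -0.03 and 1.03. Class II genes lay at 3.05 and 2.87 against 0.55 and 1.22. So hCD4+ pro-B arrays stayed under both pre-pro-B groups in these lists. Rims1 differed by 4.86 (standard error 1.04, adjusted p = 0.0149), Elk4 by 4.86 (1.00, adjusted p = 0.0128) at 1 of its 3 probes and by 0.07 at each of the others, the lipid transfer gene Pltp by 4.76 (0.73) and Cd209a by 4.49 (1.16, other probe 2.69). Pf4 differed by -5.63 (1.23, adjusted p = 0.0156), the phosphatase gene Cdc25b by -4.10 (0.26, adjusted p = 1.63e-04), Nuf2 by -3.58 (0.63) and the immediate early gene Egr1 by -3.54 (0.95). Reference genes with a difference were Cebpa (3.93, 0.70, adjusted p = 0.00711), Elane (2.99, 0.37), Flt3 (2.62, 0.47, other probes 3.52 and 0.06) and Irf8 (1.91, 0.18). Cebpa was under background in hCD4- pro-B arrays, so the size of its difference is not exact and may be smaller. Mpo stood at 3.33 (1.78, adjusted p = 0.206, other probe 4.81), Cebpe at 1.52 (0.75), Csf1r at 0.17 (0.47, other probes 2.99 and 1.04), Csf3r at 0.10 (0.27), Sfpi1 at 0.53 (0.41), Ebf1 at -0.73 (0.60), Pax5 at 0.01 (0.43), Rag1 at -0.87 (0.50, other probe 0.83) and Il7r at -0.17 (0.20), none of them called.

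Of the classical dendritic cell genes 6 of 8 had the larger change in pro-B cells, or 6 larger and 1 smaller adjusted over the list alone (median 3.15, adjusted p = 0.0103, or 0.356 with an estimated correlation). Plasmacytoid dendritic cell genes had 12 of 18, 14 adjusted over the list alone (median 1.59, adjusted p = 9.67e-06, or 0.232 with an estimated correlation), with Runx2 (4.34, 0.44). Myeloid transcription factors and receptors had 8 of 15 larger and 1 smaller, 9 and 2 adjusted over the list alone (median 1.56, adjusted p = 8.69e-04, or 0.251 with an estimated correlation), with Tyrobp (3.67, 0.49) and Fcer1g (3.61, 0.29). Class II genes had 7 of 10 larger, or 8 larger and 1 smaller adjusted over the list alone (median 1.46, adjusted p = 0.00499, or 0.295 with an estimated correlation), with Cd74 (2.75, 0.75). Smaller in pro-B cells were 21 of 22 G2/M phase genes, or 21 smaller and 1 larger adjusted over the list alone (median -2.56, adjusted p = 2.34e-17, or 0.153 with an estimated correlation). The same held for 19 of 23 S phase genes, 20 adjusted over the list alone (median -1.53, adjusted p = 3.70e-13, or 0.122 with an estimated correlation), with Rrm2 (-2.99, 0.17). Pro-B cell genes had 6 of 23 smaller, 6 adjusted over the list alone (median -0.61, adjusted p = 8.69e-04, or 0.357 with an estimated correlation), with Igll1 (-2.51, 0.41).

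The contrasts differed in 4272 genes (2417 larger and 1855 smaller in pro-B cells). The count moved to 2725 and 2280 without hCD4+ pre-pro-B replicates 1 and 2, 2722 and 2042 without hCD4- pro-B replicates 1 and 2 and 2448 without hCD4+ pro-B replicate 1. Array-median scaling put 18.0% larger in pro-B cells and cyclic loess 40.9%, against 56.6% here. The call of Rims1 ended without hCD4+ pre-pro-B replicate 2 (adjusted p = 0.0539) or hCD4- pro-B replicate 2 (0.0545; range over its alternatives 0.00478 to 0.0545). Pf4 ended without hCD4- pro-B replicate 2 (0.0548) or hCD4+ pro-B replicate 2 (0.0507; range 0.00149 to 0.0548). Cd209a ended without hCD4- pre-pro-B replicate 2 (0.0719), hCD4+ pre-pro-B replicates 1 and 2 (0.0746, 0.0712), hCD4- pro-B replicate 2 (0.0756) and hCD4+ pro-B replicates 1 and 2 (0.0789, 0.0719; range 0.00134 to 0.0789), with array weights (0.0777) and without the filter (0.0529). Egr1 ended without hCD4- pre-pro-B replicate 2 (0.0735), hCD4+ pre-pro-B replicates 1 and 2 (0.0899, 0.0629), hCD4- pro-B replicate 1 (0.0927) and hCD4+ pro-B replicates 1 and 2 (0.0809, 0.0823; range 0.00817 to 0.0927) and without the filter (0.0583).

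From hCD4- pre-pro-B to hCD4- pro-B arrays, pro-B cell genes rose and dendritic cell genes fell (2 against 2). Both pre-pro-B groups had all 18 plasmacytoid dendritic cell genes above background, and their dendritic cell share was not tested. Vpreb3 rose by 10.22 (standard error 0.63, adjusted p = 3.03e-06), Vpreb1 by 9.16 (0.21, adjusted p = 8.49e-08), Vpreb2 by 9.15 (0.37; above background on 1 of 2 pre-pro-B arrays), the coactivator gene Pou2af1 by 9.07 (0.61), Cd81 by 8.26 (0.32), Cd79a by 7.48 (0.28, other probe 6.22), Anxa1 by 7.25 (0.21) and Pde2a by 7.01 (0.13). Lef1 was at least 848-fold higher, Igll1 at least 843-fold, Gfra2 at least 716-fold, Ebf1 at least 308-fold and Pax5 at least 11.4-fold (log2 change 5.62, other probe 3.04), and Rag1 rose by 6.93 (0.35, other probe 5.55). The largest falls were those of the dendritic cell genes Itgax (-8.53, 0.68, adjusted p = 1.40e-05), Cd209a (-8.01, 0.82, other probe -5.17) and Clec10a (-7.91, 0.70) and of Pkdcc (-8.34, 0.61), Slc41a2 (-8.11, 0.32), Cd7 (-8.07, 0.40), Cybb (-8.01, 0.53) and Rnd3 (-7.98, 0.46). Pkdcc, Slc41a2, Cd209a, Cybb and Rnd3 were above background on 1 of 2 pro-B arrays. Ptprf was at least 202-fold lower, Cdh5 at least 146-fold, Rtn4rl1 at least 138-fold, Pira11 at least 136-fold and Cebpa at least 14.4-fold. Irf8 (-4.55, 0.12) and Flt3 (-4.39, 0.33, other probes -5.04 and -0.15) fell too, while Il7r stood at -0.25 (0.14, adjusted p = 0.163). Cebpe was at least 1.23-fold higher (adjusted p = 0.0155), a call that ended without hCD4- pre-pro-B replicate 2 (0.0653) or hCD4- pro-B replicate 1 (0.0927; range over its alternatives 4.53e-04 to 0.0927), with array weights (0.0655) and with normexp and quantile normalization (0.0525).

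Pro-B cell genes had 20 of 23 higher in hCD4- pro-B than in hCD4- pre-pro-B arrays (median 4.81, adjusted p = 3.13e-09, or 0.156 with an estimated correlation). S phase genes had 22 of 23 higher (median 2.95, adjusted p = 2.18e-10, or 0.122 with an estimated correlation) and G2/M phase genes 21 of 22 (median 3.31, adjusted p = 2.25e-10, or 0.232 with an estimated correlation), Rrm2 by 4.23 (0.12) and Ccnb1 by 3.79 (0.17). Erythroid genes had 8 of 10 higher and 1 lower (median 1.93, adjusted p = 0.0250, or 0.232 with an estimated correlation), with Car2 (5.50, 0.24). Basophil, mast cell and eosinophil genes had 7 of 11 higher (median 2.78, adjusted p = 0.0351, or 0.221 with an estimated correlation), with Prss34 at least 20.1-fold and Mcpt8 at least 9.84-fold higher. Plasmacytoid dendritic cell genes were lower in 18 of 18 (median -4.39, adjusted p = 1.88e-09, or 0.153 with an estimated correlation) and classical dendritic cell genes in 7 of 8, with 1 higher (median -5.97, adjusted p = 0.00104, or 0.251 with an estimated correlation). Class II genes had 9 of 10 lower and 1 higher (median -2.79, adjusted p = 3.92e-04, or 0.232 with an estimated correlation). Myeloid transcription factors and receptors had 9 of 15 lower and 2 higher (median -2.85, adjusted p = 0.00154, or 0.269 with an estimated correlation), with Tyrobp lower (-7.17, 0.35). In these lists the counts adjusted over the list alone were the same. In all 11069 genes differed (6074 higher, 4995 lower), and without the filter on dim genes 37.1% of the changed genes were higher, against 54.9% here. The basophil list's call ended without hCD4- pre-pro-B replicate 1 (0.0668) or hCD4+ pro-B replicates 1 and 2 (0.0652, 0.0682; range over its alternatives 0.00895 to 0.0682).

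Between hCD4+ pro-B and hCD4+ pre-pro-B arrays some of the same B lineage genes rose, while Cebpa stood at -1.21 (standard error 0.49, adjusted p = 0.0686, n = 2 each). Pou2af1 rose by 9.87 (0.61, adjusted p = 7.09e-06), Lef1 by 9.59 (0.71), Vpreb3 by 9.44 (0.63) and Igll1 by 9.38 (0.29), with Pou2af1, Lef1 and Igll1 above background on 1 of 2 pre-pro-B arrays. Ebf1 was at least 307-fold higher. The list of B lineage transcription factors was not called (median 1.24, adjusted p = 0.307). Sh3bgr (-4.76, 0.27, adjusted p = 5.17e-06), Cdh5 (-4.54, 0.29), Gpr162 (-4.52, 0.36) and Ddr1 (-4.38, 0.58) fell. Cebpe rose by 3.37 (0.53) and Elane by 2.42 (0.26), while Irf8 (-2.64, 0.12), Flt3 (-1.76, 0.33, other probes -1.52 and -0.09) and Il7r (-0.42, 0.14, adjusted p = 0.0342) fell. Mpo stood at 2.69 (1.26, adjusted p = 0.105). The call of Il7r ended without hCD4+ pre-pro-B replicates 1 and 2 (0.0751, 0.144) or hCD4+ pro-B replicate 2 (0.169; range over its alternatives 0.00433 to 0.169), without the filter (0.0783) or with only the arrays compared (0.0540).

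Pro-B cell genes had 20 of 23 higher and 1 lower in hCD4+ pro-B than in hCD4+ pre-pro-B arrays, the same adjusted over the list alone (median 4.09, adjusted p = 1.03e-08, or 0.165 with an estimated correlation). The rise of cell cycle genes was smaller than between the hCD4- groups: 22 of 23 S phase genes (median 1.28, adjusted p = 3.28e-07, or 0.153 with an estimated correlation) and 15 of 22 G2/M phase genes (median 0.85, adjusted p = 8.06e-04, or 0.483 with an estimated correlation), the same adjusted over the list alone. Basophil, mast cell and eosinophil genes had 8 of 11 higher, 8 adjusted over the list alone (median 3.93, adjusted p = 0.00154, or 0.122 with an estimated correlation), with Prss34 (5.88, 0.54). Lower were 15 of 18 plasmacytoid dendritic cell genes (median -2.87, adjusted p = 1.06e-08, or 0.153 with an estimated correlation) and 7 of 8 classical dendritic cell genes (median -2.55, adjusted p = 6.78e-04, or 0.249 with an estimated correlation), the same adjusted over the list alone. Class II genes had 8 of 10 lower and 1 higher (median -2.10, adjusted p = 6.90e-04, or 0.232 with an estimated correlation), and myeloid transcription factors and receptors 8 of 15 lower and 2 higher (median -1.21, adjusted p = 0.00567, or 0.330 with an estimated correlation), again the same adjusted over the list alone. Interferon response genes had 10 of 20 lower and 4 higher, 10 and 6 adjusted over the list alone (median -0.69, adjusted p = 0.0250, or 0.528 with an estimated correlation), with Mx1 (-3.55, 0.17) and, higher, Rtp4 (5.16, 0.24). That call ended under array-median scaling (adjusted p = 0.100; range over its alternatives 0.0140 to 0.100) and cyclic loess (0.0727). In all 10049 genes differed (6135 higher, 3914 lower). Array-median scaling put 39.2% of them higher and cyclic loess 48.0%, against 61.1% here, and the median of all genes was 0.25 here, -0.08 and 0.02 under those scalings.

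From hCD4- pro-B to pre-B arrays, B cell maturation genes rose and neutrophil secondary granule and progenitor genes fell (2 against 2). Agbl1 rose by 3.64 (standard error 1.22, adjusted p = 0.0433), Rims1 by 3.63 (0.74), the collagen genes Col25a1 and Col5a3 by 3.60 (0.28, other probe 1.70) and 3.54 (0.33), the signalling gene Rasgrp1 by 3.48 (0.22, adjusted p = 3.43e-05), Gcom1 by 3.33 (0.62), Stac by 3.29 (0.34) and Prm1 by 3.24 (0.48). Agbl1, Gcom1 and Stac were above background on 1 of 2 pro-B arrays. Rdh1 was at least 8.06-fold higher, Dusp26 at least 6.24-fold, Egfl6 at least 6.00-fold and Sspn at least 5.41-fold. Igh-VJ558 (-10.13, 1.58, adjusted p = 0.00174, other probes -10.41, -5.65 and 0.78), S100a9 (-7.75, 1.44, adjusted p = 0.00381), the mast cell protease gene Prss34 (-5.30, 0.54), Tmem119 (-4.16, 0.16) and Aqp1 (-4.11, 0.62) fell, each above background on 1 of 2 pre-B arrays. Ctla2a (-3.99, 0.48), Gpr97 (-3.92, 0.26) and Emp1 (-3.79, 0.38) fell as well. S100a8 was at least 112-fold lower, Igj at least 105-fold, Ltf at least 13.5-fold, Pf4 at least 12.7-fold and Cebpe at least 1.59-fold. Il7r rose by 0.74 (0.14, adjusted p = 0.00442), Elane by 0.92 (0.26, adjusted p = 0.0221) and Sfpi1 by 0.99 (0.29, adjusted p = 0.0262), and Flt3 changed by -2.55 (0.33, other probes -3.88 and 0.73).

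Pre-B and later B cell genes had 17 of 19 higher in pre-B than in hCD4- pro-B arrays, 17 adjusted over the list alone (median 2.18, adjusted p = 2.46e-08, or 0.122 with an estimated correlation), with Cd2 (3.23, 0.23), Faim3 (3.02, 0.22) and Il2ra (2.90, 0.33). Class II genes had 7 of 10 higher and 1 lower, the same adjusted over the list alone (median 1.55, adjusted p = 0.00603, or 0.309 with an estimated correlation), with their regulator Ciita (2.51, 0.19). Their median was 0.82 with levels under the detection floor set to that floor. Neutrophil secondary granule and late genes had 10 of 14 lower and 1 higher, 11 and 1 adjusted over the list alone (median -2.35, adjusted p = 5.73e-04, or 0.232 with an estimated correlation). Stem and multipotent progenitor genes had 9 of 14 lower, 9 adjusted over the list alone (median -2.00, adjusted p = 7.09e-04, or 0.232 with an estimated correlation), with Kit (-3.62, 0.18) and Egfl7 (-3.42, 0.21). Glycolysis genes had 11 of 16 lower, 14 adjusted over the list alone (median -0.87, adjusted p = 4.98e-05, or 0.232 with an estimated correlation), with Pfkm (-1.63, 0.16) and Ldha (-1.60, 0.13). Interferon response genes had 13 of 20 lower and 1 higher, 15 and 1 adjusted over the list alone (median -1.03, adjusted p = 3.29e-04, or 0.339 with an estimated correlation). S phase genes had 11 of 23 lower, or 12 lower and 1 higher adjusted over the list alone (median -0.44, adjusted p = 8.69e-04, or 0.260 with an estimated correlation). T cell genes had 6 of 12 lower, 6 adjusted over the list alone (median -0.75, adjusted p = 0.0272, or 0.201 with an estimated correlation), with Thy1 (-3.40, 0.17) and Lat (-2.31, 0.19).

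In all 7621 genes differed between pre-B and hCD4- pro-B arrays (3654 higher, 3967 lower), 4686 without hCD4- pro-B replicate 2 and 4693 without pre-B replicate 2, and array-median scaling put 34.8% higher against 47.9% here. The T cell list's call ended without pre-B replicate 1 (0.0905; range over its alternatives 0.00405 to 0.0905). Elane ended without pre-B replicate 2 (0.123) or hCD4- pro-B replicates 1 and 2 (0.0703, 0.0989; range 0.00585 to 0.123). Sfpi1 ended without pre-B replicates 1 and 2 (0.0823, 0.105) or hCD4- pro-B replicates 1 and 2 (0.0901, 0.0982; range 0.00606 to 0.190). Its rise was smaller and not called with normexp and quantile normalization (0.41, adjusted p = 0.0677), quantile normalization (0.87, adjusted p = 0.0663), array-median scaling (0.80, adjusted p = 0.0858), cyclic loess (0.62, adjusted p = 0.190) and in the authors' table (0.40, adjusted p = 0.0921), and without the filter the call ended too (0.0508). Agbl1 ended without pre-B replicates 1 and 2 (0.121, 0.142), hCD4- pro-B replicate 2 (0.232), either hCD4- pre-pro-B array (0.0524) or either hCD4+ pro-B array (0.0642; range 0.00468 to 0.232), and under quantile normalization (0.0618), cyclic loess (0.0699) or no filter (0.0761).

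GMP arrays differed from hCD4+ pre-pro-B arrays by granule and mast cell genes that were higher and lymphoid and dendritic genes that were lower (2 against 2). Ms4a3 rose by 9.04 (standard error 0.57, adjusted p = 4.81e-06), Cebpe by 8.25 (0.53, adjusted p = 5.05e-06), Cpa3 by 7.49 (0.48), Prg2 by 7.40 (1.25), Prtn3 by 7.21 (0.54), Hk3 by 7.15 (0.32), Igsf6 by 7.15 (0.37) and Gda by 7.11 (0.24, other probe 5.99). Cebpe, Cpa3 and Prg2 were above background on 1 of 2 pre-pro-B arrays. The histamine-forming enzyme gene Hdc was at least 308-fold higher, Mgst1 at least 138-fold, Gatm at least 88.0-fold and Trem3 at least 87.4-fold. The largest falls were those of Cd7 (-10.31, 0.40, adjusted p = 3.33e-07), Epha2 (-9.34, 0.19), H2-Eb1 (-9.26, 0.42), Egfbp2 (-9.07, 0.84), Cd74 (-9.01, 0.53), Blnk (-8.93, 0.15) and Itgax (-8.72, 0.68). Cd7, Epha2, H2-Eb1, Egfbp2 and Cd74 were above background on 1 of 2 GMP arrays. Ly6d was at least 5200.02-fold lower, Spib at least 1448-fold, Ccr9 at least 831-fold (log2 change -11.39, other probe -8.56), Klk1b5 at least 488-fold and Il7r at least 263-fold. Cebpa rose by 2.27 (0.49, adjusted p = 0.00461), Elane by 7.03 (0.26), Mpo by 4.64 (1.26, adjusted p = 0.0139, other probe 7.36) and Csf1r by 2.85 (0.33, other probes 1.41 and 0.42), while Irf8 (-2.36, 0.12) and Flt3 (-3.74, 0.33, other probes -3.78 and -1.59) fell.

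Primary granule genes had 13 of 14 higher in GMP than in hCD4+ pre-pro-B arrays, 14 adjusted over the list alone (median 5.58, adjusted p = 1.18e-06, or 0.122 with an estimated correlation). In the lists that follow, counts adjusted over the list alone were the same unless given. Basophil, mast cell and eosinophil genes had 10 of 11 higher (median 6.47, adjusted p = 1.61e-05, or 0.122 with an estimated correlation). S phase genes had 21 of 23 higher (median 1.12, adjusted p = 2.91e-06, or 0.165 with an estimated correlation). Glycolysis genes had 13 of 16 higher and 1 lower (median 1.59, adjusted p = 2.32e-04, or 0.251 with an estimated correlation), and stem and multipotent progenitor genes 9 of 14 higher and 1 lower (median 1.79, adjusted p = 0.0113, or 0.328 with an estimated correlation). Monocyte genes had 9 of 13 higher and 2 lower, 9 and 3 adjusted over the list alone (median 1.53, adjusted p = 0.0485, or 0.332 with an estimated correlation). Lower were 18 of 18 plasmacytoid dendritic cell genes (median -5.45, adjusted p = 3.07e-11, or 0.122 with an estimated correlation), 7 of 8 classical dendritic cell genes (median -4.88, adjusted p = 3.92e-04, or 0.232 with an estimated correlation) and 10 of 10 class II genes (median -3.16, adjusted p = 1.56e-06, or 0.153 with an estimated correlation). Lower too were 15 of 19 pre-B and later B cell genes (median -3.19, adjusted p = 2.59e-08, or 0.122 with an estimated correlation), 12 of 15 early lymphoid progenitor genes (median -1.59, adjusted p = 8.42e-07, or 0.122 with an estimated correlation) and 11 of 16 B lineage transcription factors (median -1.76, adjusted p = 9.67e-06, or 0.122 with an estimated correlation). T cell genes had 8 of 12 lower (median -2.07, adjusted p = 5.01e-04, or 0.122 with an estimated correlation), plasma cell genes 5 of 7 (median -1.62, adjusted p = 0.00672, or 0.259 with an estimated correlation), interferon response genes 13 of 20 with 3 higher (median -2.08, adjusted p = 1.29e-04, or 0.320 with an estimated correlation) and pro-B cell genes 12 of 23 with 4 higher (median -0.81, adjusted p = 0.00314, or 0.431 with an estimated correlation).

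In all 10048 genes differed between GMP and hCD4+ pre-pro-B arrays (5815 higher, 4233 lower), and cyclic loess put 47.5% higher against 57.9% here. The call of Mpo ended without GMP replicate 2 (adjusted p = 0.0633) or hCD4+ pre-pro-B replicate 1 (0.0821; range over its alternatives 7.31e-05 to 0.0821). The monocyte list ended without GMP replicate 1 (0.0577), hCD4+ pre-pro-B replicate 1 (0.0625), hCD4+ pro-B replicates 1 and 2 (0.0570, 0.0598) and pre-B replicates 1 and 2 (0.0531, 0.0519; range 0.0169 to 0.0625). It also ended under quantile normalization (0.0514), array-median scaling (0.0589) and with the replicate number as a block (0.0563).

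Between GMP and pre-B arrays 12070 genes changed (5682 higher in GMP, 6388 lower). Cebpa was at least 80.4-fold higher in GMP (7.70, standard error 0.49, n = 2 each, adjusted p = 3.40e-06) and Cebpe at least 424-fold, while Mpo rose by 9.91 (1.26, other probe 13.14), Elane by 6.78 (0.26), Csf1r by 4.67 (0.33, other probes 4.30 and -0.40), Flt3 by 3.21 (0.33, other probes 4.28 and -1.65) and Irf8 by 1.50 (0.12). Ebf1 was at least 435-fold lower, Il7r at least 415-fold, Rag1 at least 409-fold (log2 change -10.02, other probe -8.66) and Pax5 at least 19.98-fold (log2 change -6.13, other probe -3.98). Myeloid transcription factors and receptors had 14 of 15 higher and 1 lower, the same adjusted over the list alone (median 4.04, adjusted p = 1.56e-06, or 0.153 with an estimated correlation). Pro-B cell genes had 20 of 23 lower, 20 adjusted over the list alone (median -7.47, adjusted p = 8.75e-11, or 0.153 with an estimated correlation), and B lineage transcription factors 15 of 16 lower and 1 higher, the same adjusted over the list alone (median -5.37, adjusted p = 1.45e-06, or 0.122 with an estimated correlation). Array-median scaling put 65.6% of the changed genes higher against 47.1% here.

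Comparisons within a slide hold the slide constant but pair groups of different kinds (2 against 2). On slide 3, pre-B against hCD4+ pro-B arrays changed 7955 genes (3493 higher, 4462 lower). There monocyte genes had 9 of 13 lower and 1 higher (median -2.35, adjusted p = 6.46e-05, or 0.0951 with an estimated correlation), primary granule genes 10 of 14 lower and 2 higher (median -1.85, adjusted p = 0.00162, or 0.150 with an estimated correlation) and myeloid transcription factors and receptors 10 of 15 lower and 1 higher (median -1.88, adjusted p = 0.00252, or 0.220 with an estimated correlation). Classical dendritic cell genes had 6 of 8 lower and 1 higher (median -3.38, adjusted p = 0.0481, or 0.398 with an estimated correlation). Plasmacytoid dendritic cell genes, with 11 of 18 lower and 3 higher (median -1.29, adjusted p = 0.0792), were not called, nor were class II genes, with 2 of 10 lower and 4 higher, 2 and 5 adjusted over the list alone (median 0.75, adjusted p = 0.173). Pre-B and later B cell genes had 15 of 19 higher, 16 adjusted over the list alone (median 1.72, adjusted p = 1.71e-08, or 0.0951 with an estimated correlation). On slide 2, hCD4- pro-B against hCD4+ pre-pro-B arrays changed 8869 genes (5421 higher, 3448 lower). Pro-B cell genes had 20 of 23 higher (median 4.39, adjusted p = 6.91e-11, or 0.0951 with an estimated correlation), and S phase genes 22 of 23 higher (median 1.14, adjusted p = 4.94e-07, or 0.104 with an estimated correlation). Plasmacytoid dendritic cell genes had 16 of 18 lower, 17 adjusted over the list alone (median -3.96, adjusted p = 6.91e-11, or 0.0951 with an estimated correlation). On slide 1, GMP against hCD4- pre-pro-B arrays changed 12152 genes (6444 higher, 5708 lower). Primary granule genes had 14 of 14 higher (median 7.82, adjusted p = 1.67e-06, or 0.0951 with an estimated correlation), S phase genes 22 of 23 (median 2.99, adjusted p = 1.80e-09, or 0.0951 with an estimated correlation) and G2/M phase genes 19 of 22 (median 2.24, adjusted p = 3.28e-07, or 0.220 with an estimated correlation). Where no count adjusted over the list alone is given, it was the same.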

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

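The tests of explanations in this part were chosen after the results were seen, except the one that asks whether any group has arrays on both slides 1 and 2. Bootstrap intervals here and below resample the genes of a set (2000 draws). They treat its genes as independent and do not hold the spread between arrays, so they can be too narrow. Results here are singled out by a test of the difference of the hCD4 contrasts, over 8 arrays in 4 groups. Both slide 2 groups enter it with the same sign, so slide 2 alone may give a difference. By this test their hCD4 change differed between pro-B and pre-pro-B cells. This held for 4272 genes, among them Rims1 (4.86 on the log2 scale, larger in pro-B cells), Elk4 (4.86 at 1 of its 3 probes, 0.07 at each of the others), Pltp (4.76), Cd209a (4.49, other probe 2.69), Cebpa (3.93, not exact since hCD4- pro-B arrays were under background), Elane (2.99), Flt3 (2.62, other probes 3.52 and 0.06) and Irf8 (1.91). It held in the other direction for Pf4 (-5.63), Cdc25b (-4.10), Nuf2 (-3.58) and Egr1 (-3.54). The lists were classical dendritic cell genes (median 3.15), plasmacytoid dendritic cell genes (1.59), myeloid transcription factors and receptors (1.56) and class II genes (1.46) on the one side. On the other were G2/M phase genes (-2.56), S phase genes (-1.53) and pro-B cell genes (-0.61). With an estimated correlation none of these lists was called (adjusted p = 0.122 to 0.357). For the dendritic, class II and myeloid factor lists, median levels in hCD4+ pro-B arrays lay under those of either pre-pro-B group.

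The first pattern is that myeloid and dendritic genes were higher in hCD4+ than in hCD4- pro-B arrays. A slide effect alone would raise them in pre-B arrays too, which share slide 3 with the hCD4+ pro-B arrays. The 146 genes restricted to GMP were at least 4 higher on the log2 scale in GMP than in hCD4- pro-B and hCD4+ pre-pro-B arrays. From hCD4- pro-B to pre-B arrays they changed by a median of 0.14 (95% bootstrap interval 0.01 to 0.17) against 1.76 in the hCD4 contrast. The 41 genes of the myeloid factor, monocyte and primary granule lists changed by 0.0601 (-0.60 to 0.35) against 1.50. The 8 classical dendritic cell genes changed by 0.45 (-1.80 to 0.94) against 3.095. Thus these sets showed no rise of that size in pre-B arrays. The 18 plasmacytoid dendritic cell genes changed by 0.57 (-0.41 to 0.82) against 1.22, and the 10 class II genes by 1.55 (0.24 to 2.33) against 1.28. With levels under the detection floor set to that floor, the class II medians were 0.82 and 1.02. Pre-B cells also differ by maturation, and a fall with maturation could offset a slide rise, so the slide effect stays open for all these genes. A candidate explanation is that the sort held a small fixed share of GMP-like cells. Of the 145 GMP-restricted genes other than Mpo, 63.4% implied a share within 2-fold of their median share of 4.08%, among them Prtn3 (5.01%) and Elane (3.65%). The brighter Mpo probe implied 25.8% (21.0 to 31.6 over 8 pairings of single arrays) and the other 6.62%, which leaves Mpo open. A share of cells like those of the hCD4+ pre-pro-B gate stays open as well, since 76.1% of 197 genes restricted to that gate implied a share within 2-fold of 5.67%. Another 235 genes lay at least 4 higher on the log2 scale in hCD4- pro-B than in GMP and hCD4+ pre-pro-B arrays. They stood at -0.98 in the hCD4 contrast, against the -0.15 that dilution by both shares gives. They were picked by the same hCD4- arrays that the contrast starts from, which favours a fall, so this gap does not judge dilution. Pro-B cell genes, a list fixed beforehand, stood at a median of -0.51. Whether single pro-B cells carry the myeloid and dendritic transcripts was not measured. With the slide and these shares open, the pattern is not called biological.

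The second pattern is that proliferation genes and some myeloid genes were higher in hCD4+ than in hCD4- pre-pro-B arrays. Less RNA on the dimmer hCD4- arrays would lower dim genes, and the 4639 dimmest genes shifted by a median of -0.33 and the 4639 brightest by 0.02, a trend opposite to the pattern. Relative to genes of the same level 72 members of the S phase, G2/M phase, primary granule and monocyte lists, whether or not they passed alone, still had a median change of 1.95 (interval 1.52 to 2.27). This argues only against a shift shared by genes of the same level as the whole cause. The lists were pooled because they rose here, and neither other effects of less RNA nor dendritic shares were tested. A share of GMP-like cells would have to make up 64.3% of the RNA (interval 39.4 to 88.2, 45 genes) to give the S and G2/M phase genes their rise, which argues against it there, while for myeloid genes it stays open. For this contrast 142 GMP-restricted genes were chosen against hCD4- pro-B and hCD4- pre-pro-B arrays. Of these 13.4% implied a share within 2-fold of their median share of 0.219%, and 42.3% at most 1/10 of it, which goes against a fixed share, but the baseline of most of them would hide so small a share. Of the 32 whose signal the lower share that an Mpo probe implied (0.584%, the other 3.92%) would at least double, 43.8% lay within 2-fold of their median share of 0.590%, and 65.6% (interval 46.9 to 81.3) implied at least 1/2 of that lower Mpo share. Slide 2 and slide 1 cannot be told apart from the groups, since 0 groups have arrays on both, so this pattern is not called biological either.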

How the results depend on the processing

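The alternatives were chosen beforehand except those named above as added after the data were seen. Where leaving out an array left 1 in a group, that array was taken to vary like the others. The slide and scan date blocks were not run.

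Without 1 array the count of changed genes ran from 1120 to 5319 in the pre-pro-B contrast (3162 with all), 1460 to 4721 in the pro-B contrast (3802), 2042 to 6080 for their difference (4272) and 4686 to 8643 for pre-B against hCD4- pro-B arrays (7621). The ranges were 8977 to 11510 for the hCD4- gates (11069), 7824 to 10945 for the hCD4+ gates (10049), 8287 to 10757 for GMP against hCD4+ pre-pro-B (10048) and 10138 to 12736 for GMP against pre-B arrays (12070). List calls ran from 81 to 90 (83). A fit to the 4 arrays compared gave 485 in the pre-pro-B contrast and array weights gave 1394. Requiring a log2 change of at least 1 left 1427, 1631 and 2863 in the hCD4 contrasts and their difference, 6627 and 5379 between the gates, 3496 for pre-B against hCD4- pro-B, 5699 for GMP against hCD4+ pre-pro-B and 7547 for GMP against pre-B arrays, as fewer genes can pass. Of the lists camera with an estimated correlation called 0 and fry 134. The direction reversed for Pax5 in the difference of the contrasts in the authors' table (-0.45, adjusted p = 0.0470; 0.01 here). With fry it reversed or differed from the test here for monocyte genes between the hCD4- gates (median -1.26, 0.0127) and the hCD4+ gates (-0.25, 0.0304) and for early lymphoid progenitor genes between the hCD4+ gates (-0.42, 0.00273). The cause was not tested.

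The calls of 147 of 178 called results of named genes held under every alternative run for them, 31 ended somewhere, and 32 of 52 that were not called passed somewhere. The stricter filter kept the genes of 212 of these 230 results, so the others were not tested under it. Of 83 list calls 74 held under every setting other than the estimated correlation and fry, 9 ended somewhere, and 28 of 109 others passed somewhere. No called list median changed sign, also with levels under the detection floor set to that floor (83 of 83), where 15 moved by over 0.5. Among these were those of basophil, mast cell and eosinophil genes (2.78 to 1.15 and 3.93 to 2.40 between the gates) and of the interleukin 7 list in the pre-pro-B contrast (0.54 to 0.00). The 4 results of the GMP and pre-B genes kept their calls under every setting but the estimated correlation, where GMP genes in the pre-pro-B contrast lost theirs (camera p = 5.74e-04, or 0.147 with an estimated correlation). Their medians without 1 array ran from 0.02 to 0.15 in the pre-pro-B and from 0.56 to 0.61 in the pro-B contrast for GMP genes. The counts behind them moved more. Over all alternatives the GMP genes that rose numbered 30 to 542 in the pre-pro-B contrast (230 here) and 337 to 679 in the pro-B contrast (578), and the pre-B genes that fell 68 to 437 (304) and 295 to 646 (530).

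The replicate number was not treated as pairing, although the series title names 2 mice. Deviations from the group mean correlated between arrays of the same number at -0.01 to 0.25, above 0.1 in 10 of 15 pairs of groups, so a shared source is not excluded. With it as a block the counts were 3542, 4093, 4793, 11487, 10400, 8104, 10420 and 12516 in the order of the report. The calls of Cd34, the pre-B list and the monocyte list given above ended.

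Scaling to the array median moved the median of all genes to 0.24 in the pre-pro-B contrast (-0.06 here), -0.19 in the pro-B contrast (0.02), -0.46 for their difference (0.06), 0.22 for the hCD4- gates (0.02), -0.16 for pre-B against hCD4- pro-B (0.03), 0.25 for GMP against hCD4+ pre-pro-B (0.10) and 0.32 for GMP against pre-B arrays (-0.13). Cyclic loess moved it to 0.06 in the pre-pro-B contrast, -0.10 for the difference, -0.02 for GMP against hCD4+ pre-pro-B and -0.01 for GMP against pre-B arrays. Quantile normalization gave 0.09 and normexp 0.06 between the hCD4+ gates. Without the filter it was -0.37, 0.47, -0.48 and 0.19 in the pre-pro-B contrast, the difference, the hCD4- gates and pre-B against hCD4- pro-B arrays. A fold against a group in which no array was above background is a lower bound.

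All kept probes of a gene had the same sign for 75.6% of 685 changed genes with several probes in the pre-pro-B contrast, 84.3% of 778 in the pro-B contrast and 72.7% of 921 for the difference.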

Other observations

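The immunoglobulin list and the plasma cell test in this part were chosen after the results were seen. Immunoglobulin genes, taken as 98 genes by their array description, were lower in hCD4+ arrays of both gates: 41 fell and 1 rose in pre-pro-B cells, 53 and 1 adjusted over the list alone (median -1.51, camera p = 6.40e-19, or 0.0379 with an estimated correlation). In pro-B cells 36 fell and 0 rose, 43 and 0 adjusted over the list alone (median -0.99, p = 1.59e-14, or 0.0617 with an estimated correlation). From hCD4- pro-B to pre-B arrays 37 rose and 11 fell (median 0.85). The difference of the hCD4 contrasts had a median of 0.25. Igj lay at 1.96 in hCD4- pre-pro-B and 2.16 in hCD4- pro-B arrays, at -3.53 and -5.18 in the hCD4+ groups, and under background in GMP and pre-B arrays.

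Both cell cycle lists were lowest in hCD4- pre-pro-B arrays. The median level of S phase genes was 1.22 in hCD4- pre-pro-B arrays, 2.93 in hCD4+ pre-pro-B, 3.69 in pre-B, 4.18 in hCD4- pro-B, 4.24 in GMP and 4.40 in hCD4+ pro-B arrays. For G2/M phase genes it was -0.20 in hCD4- pre-pro-B, 1.90 in GMP, 2.02 in hCD4+ pre-pro-B and 3.07 to 3.14 in the other groups. Csf3r, a receptor of the neutrophil lineage, lay between 6.28 and 7.08 in all 6 groups, GMP lowest. What that probe measures was not tested, so the gene need not be expressed alike.

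The third pattern is the fall of immunoglobulin and Igj transcripts in hCD4+ arrays of both gates. Plasma cells among the hCD4- sorted cells may be its source, and would bring their other transcripts as well. The plasma cell list without Igj (6 genes) had a median of -0.25 (95% bootstrap interval -0.46 to 0.18) in pre-pro-B and -0.32 (-0.82 to 0.76) in pro-B cells. These intervals leave the explanation open, the sort markers that would remove such cells are not given by the labels, and no biological explanation was tested.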
